A study of Homo sapiens with 12 samples.

How the data were processed

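Stranded total RNA libraries depleted of ribosomal RNA were made from MDA-MB-231, an established human breast adenocarcinoma cell line. There were 12 libraries, 3 for each of 4 media kept on the cells for 36 h with 3% serum after growth in 10% serum. The full medium held 25 mM glucose and 4 mM glutamine, the glucose-only medium lacked glutamine, the glutamine-only medium lacked glucose, and the deficient medium lacked both. The labels give each library a replicate letter, A, B or C, and do not state whether the 3 libraries of a medium came from separate cultures. The p-values below therefore measure the spread between libraries whose independence as cultures is not stated.

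The deposited values are gene-level signal: numbers of reads per gene divided by 1 size factor per library, computed by the authors. Per the labels the processing used FastQC, HISAT2, Subread and DESeq2 with genome build GRCh38.p14, with no versions, annotation release or strand setting given. In every library 100% of the values were whole multiples of 1 step within a tolerance of 0.01 reads, so that the numbers of reads could be recovered. The recovered reads totalled 875033 to 1473587 per library, and 1 read corresponded to a deposited value of 0.661 to 1.30. The size factors implied by the file equalled, up to a constant, median-of-ratios factors recomputed with DESeq2 on the recovered reads. These values are called normalized counts below. The file held 63187 genes by Ensembl ID, of which 62666 matched the reference names and 42984 carried a symbol. Gene positions are those of GRCh38.p14 in a RefSeq gene table, and exon overlap was read from GENCODE release 29, which is older than the annotation behind the file.

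Genes with a normalized count of at least 10 in at least 3 of the 12 libraries were kept, which left 9270 of the 32493 genes with any read, 8539 of them protein coding. The test was limma-trend 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a pseudocount of 1, in 1 model with a mean per medium over all 12 libraries. Benjamini-Hochberg adjusted p under 0.05 over the 9270 genes was the threshold, and log2 changes are given with the moderated standard error (SE). Counts per medium are means ± SD of 3 libraries. All p-values are two-sided and adjusted unless stated. The 6 comparisons between media, the interaction (full minus glucose-only minus glutamine-only plus deficient) and the average effects of each nutrient came from the same fit. The average effects are orthogonal contrasts that share no chance covariance when the groups have equal spread.

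The 30 gene lists, the markers of other cell types, the comparisons, the tests and the rule for named genes were fixed before the data were examined. The lists held 757 distinct genes of the file, 613 of which were tested, and some genes stand in several lists. The rule names the 5 highest and 5 lowest log2 changes in each main comparison, and the 3 highest and lowest in each secondary comparison and the interaction. It takes them among genes past the threshold with a mean of at least 100 and a symbol that is not a clone, noncoding-locus or pseudogene name, and, except for the interaction, with no overlap between the groups. It adds up to 4 members of each described list with the largest changes, and fixed anchor genes such as TXNIP, TRIB3, HSPA5 and SCD. Lists were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 30 lists within each comparison. Camera compares a list's members with all other genes. Each list is given with its members past the threshold over all genes and with the number passing when adjusted over the list alone. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without reference to other genes, were the alternatives.

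Alternatives changed 1 choice at a time: pseudocounts of 0.5 and 8, no filter, a mean of at least 100, equal totals, quantile normalization, a block for the replicate letter, fits on the 2 groups alone, a constant prior variance, each library left out, and adjusted p under 0.01. Tests on recovered reads used edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald). Median-of-ratios scaling on protein-coding genes and a fit on nuclear protein-coding genes were added after seeing the data. Equal totals moved the median change of all genes by over 0.1 in 7 of the contrasts, with shifts of -0.39 for deficient against full, -0.21 for glucose-only against full and -0.12 for glutamine-only against full. The shifts were 0.17 and 0.27 for glucose-only and glutamine-only against deficient, and 0.14 and 0.24 for the average glucose and glutamine effects.

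The procedure was tested on simulated reads with 200 changed genes in the deficient group. It called 25% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 100% of those changed 4-fold, and 8 of 8880 unchanged genes. The simulated reads had 1 dispersion of 0.0075 for all genes and no shift in composition. Far more genes were called in the data, so these shares do not carry over to the comparisons below. Genes with near-identical copies elsewhere in the genome (histones, ribosomal protein genes with their pseudogenes, heat shock paralogs and mitochondrial genes) carry values that depend on how multiply mapped reads were handled, which is not stated. Genes under the filter were not tested.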

Results

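RNA from MDA-MB-231 cells in 4 media was sequenced to 875033 to 1473587 reads assigned to genes per library, with 3 libraries per medium. This depth detected 17414 to 19817 genes per library, and 1213 genes reached a mean normalized count of 100. Markers of other cell types were low: all 9 fibroblast, 11 blood cell and 7 adipocyte markers stayed under 10 in every library. Among 7 endothelial markers 5 stayed under 10 and the highest value was 19.7. Of 12 luminal epithelial markers 6 stayed under 10 everywhere, including the oestrogen receptor gene ESR1 and the E-cadherin gene CDH1, while KRT18 and KRT8 were read in every medium, KRT18 at 242.6 in the full medium. The make-up of the RNA differed between media. Protein-coding genes took 55.4 ± 3.94% of reads in the full medium (SD, n = 3), 51.1 ± 3.34% in glutamine-only, 47.3 ± 4.34% in deficient and 44.4 ± 2.51% in glucose-only. Mitochondrial ribosomal RNA took 9.54 ± 0.939% in the full and 16 ± 0.984% in the deficient medium. The libraries were depleted of ribosomal RNA, so that this share may also depend on the depletion. Mitochondrial tRNA took 14.8 ± 0.810% in glucose-only, 11.1 ± 2.19% in deficient, 8.97 ± 1.42% in glutamine-only and 8.56 ± 1.53% in full.

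The first principal component, 48.1% of the variance, set the deficient libraries apart from the other 9, and the third, 11.2%, separated glucose-only from glutamine-only libraries. Common biological variation between libraries of a medium was 8.64%. Squared differences within pairs of libraries of a medium were 1.18 to 7.88 times the variance of sampling noise. The highest ratio was for deficient replicates B and C, and the next, 4.21, for full replicates B and C.

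**Figure D1:**
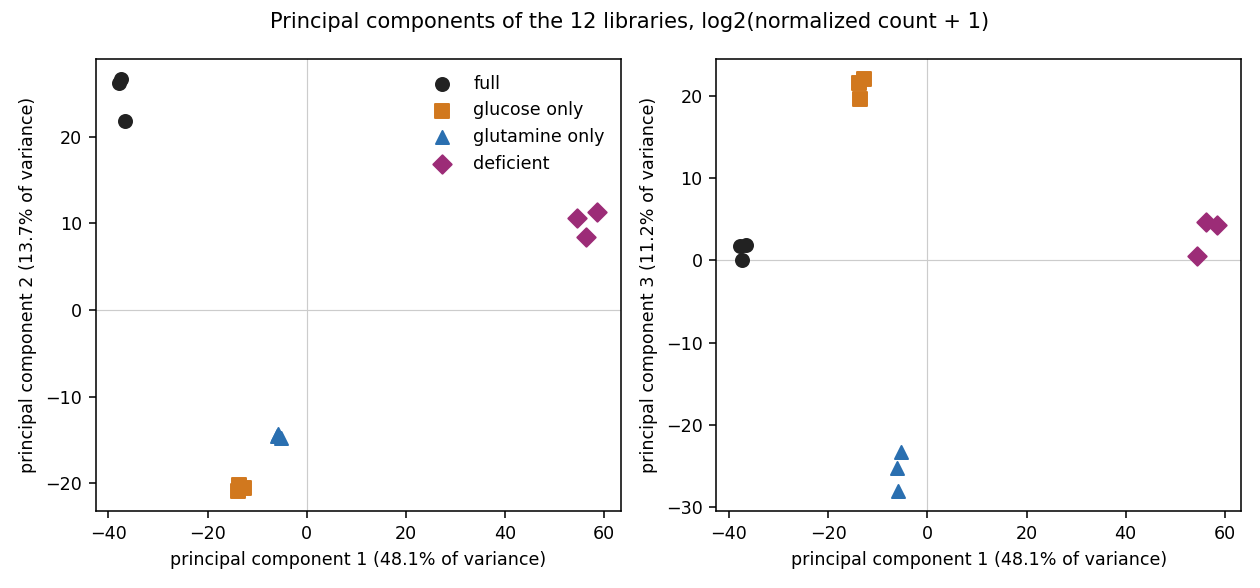
Principal component scores of the 12 libraries (log2 normalized count + 1, centred per gene; points are libraries, colours and shapes are media), component 1 against components 2 and 3. The deficient libraries have a mean score of 56.4 on component 1 and the full-medium libraries -37.3.

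The first comparison asked what the loss of both nutrients changed. Cells without glucose and glutamine raised cytosolic heat shock genes, whose products hold and refold unfolded proteins. DNAJB1, a co-chaperone of HSP70 (ENSG00000132002, chromosome 19, 14514769 to 14560391), went from 69.8 ± 3.40 in the full to 3487 ± 138 in the deficient medium (SD, n = 3). Its log2 change was 5.62 ± 0.11 (SE), and gene changes below are given in the same way. The abundant chaperone HSP90AA1 rose from 898 ± 37.7 to 6052 ± 491. Proliferation genes moved the other way: the proliferation marker MKI67 fell from 533 ± 11.7 to 82.8 ± 17.6, and the histone gene H3C3 (ENSG00000287080, chromosome 6, 26045384 to 26045869) from 937 ± 101 to 68.4 ± 10.0. TXNIP, an arrestin-family gene switched on by glucose (ENSG00000265972, chromosome 1, 145992435 to 145996579), fell from 123 ± 9.24 to 15.8 ± 1.08.

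In the list of heat shock genes and cytosolic chaperones 14 of 14 tested rose (median 2.24, adjusted p = 1.01e-17, 14 adjusted over the list alone; list medians are of log2 changes). HSPH1 was at 3.79 ± 0.12 and DNAJB4 at 2.68 ± 0.29. HSPA6, a strictly stress-inducible HSP70, had 3250 reads in the deficient libraries and 2 in the full ones, a ratio of 2066 (95% counting interval 571 to 17064). Its relatives HSPA1A and HSPA1B were listed at 0 to 3.91 and 0 to 1.30 per library and not tested. Both lie in the major histocompatibility region of chromosome 6, where 0 of 94 protein-coding genes that share no exonic base with another gene on the same strand reached a mean of 10, so that these values do not show that they were silent. Of the ER chaperone and unfolded protein response genes, 21 of 22 tested rose and 1 did not pass (median 1.35, adjusted p = 7.16e-13, 21 adjusted over the list alone). They included HSPA5, the main ER chaperone (ENSG00000044574, chromosome 9, 125234853 to 125241343), at 2.64 ± 0.09, and DNAJB9 at 3.26 ± 0.15. Of the targets of ATF4, the transcription factor of the amino acid response, 20 of 24 tested rose, 2 fell and 2 did not pass (median 1.75, adjusted p = 6.22e-12, 22 adjusted over the list alone). The stress hormone gene GDF15 was at 4.61 ± 0.26, the stress transcription factor DDIT3 at 4.05 ± 0.29, and the pseudokinase TRIB3 (ENSG00000101255, chromosome 20, 380760 to 397559) at 3.91 ± 0.14. Among cytosolic tRNA synthetases 13 of 17 tested rose, 1 fell and 3 did not pass (median 0.79, adjusted p = 2.09e-06, 14 adjusted over the list alone), AARS1 by 2.04 ± 0.11.

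Of ribosome biogenesis genes 24 of 28 tested rose and 4 did not pass (median 1.07, adjusted p = 1.48e-10, 25 adjusted over the list alone), with the transcription factor MYC at 2.84 ± 0.12. Of cytosolic ribosomal protein genes, whose values depend on reads shared with pseudogenes, 47 of 48 tested rose and 1 did not pass (median 0.70, adjusted p = 7.17e-17, 48 adjusted over the list alone). Of the oxidative stress targets of NRF2 13 of 21 tested rose, 1 fell and 7 did not pass (median 0.88, adjusted p = 5.12e-06, 15 adjusted over the list alone). The haem oxygenase HMOX1 was at 6.41 ± 0.44 and the ferritin gene FTL at 2.23 ± 0.11. Growth arrest genes were split: 11 of 16 tested rose and 5 fell (median 1.19, adjusted p = 0.00109, 16 adjusted over the list alone), with GADD45A at 2.68 ± 0.19 and GADD45B at 2.74 ± 0.20. Of glutamine and glutamate metabolism genes 9 of 14 tested rose and 5 did not pass (median 0.91, adjusted p = 0.00102, 9 adjusted over the list alone), with the transporter SLC38A2 at 1.53 ± 0.09. Of lysosome and autophagy genes 16 of 29 tested rose, 3 fell and 10 did not pass (median 0.62, adjusted p = 0.0108, 20 adjusted over the list alone). RRAGC (2.02 ± 0.21) and FLCN (1.86 ± 0.19) are regulators of nutrient signalling at the lysosome. Also named for the highest values were the immediate early genes EGR1 (5.52 ± 0.15) and FOS (4.45 ± 0.27).

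All 28 tested replication-dependent histone genes, which have near-identical copies, fell (median -2.97, adjusted p = 6.49e-27, 28 adjusted over the list alone), H2BC11 by -3.23 ± 0.17 and H2BC17 by -3.14 ± 0.16. All 32 tested mitosis genes fell (median -2.24, adjusted p = 7.18e-22, 32 adjusted over the list alone), among them TOP2A at -3.23 ± 0.10 and ASPM at -3.01 ± 0.13. Of DNA replication genes 23 of 30 tested fell and 7 did not pass (median -1.34, adjusted p = 2.40e-08, 24 adjusted over the list alone), with the ribonucleotide reductase subunit RRM2 at -3.57 ± 0.20. Of cholesterol synthesis genes 16 of 20 tested fell and 4 did not pass (median -1.39, adjusted p = 1.86e-08, 16 adjusted over the list alone). Of fatty acid and triglyceride synthesis genes 11 of 17 tested fell, 2 rose and 4 did not pass (median -0.70, adjusted p = 0.000229, 13 adjusted over the list alone). The desaturase FADS2 was at -2.91 ± 0.14 and SCD at -2.45 ± 0.10. Of the hypoxia targets of HIF1A 14 of 21 tested fell, 4 rose and 3 did not pass (median -1.33, adjusted p = 4.58e-05, 18 adjusted over the list alone), with CA12 at -3.19 ± 0.19. Glycolysis genes were divided: 12 of 21 tested fell, 4 rose and 5 did not pass (median -1.03, adjusted p = 5.43e-05, 16 adjusted over the list alone), with PGK1 at -2.20 ± 0.11 against the hexokinase HK2 at 1.16 ± 0.17. Of interferon-stimulated genes 10 of 13 tested fell and 3 did not pass (median -1.39, adjusted p = 0.000738, 10 adjusted over the list alone), OAS3 by -2.25 ± 0.25.

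Of the 21 lists called in this comparison, 18 were also called with an estimated correlation, and 3 with the preset value alone. Of mitochondrially encoded messenger RNAs 12 of 13 tested rose and 1 did not pass (median 0.74, adjusted p = 5.12e-06, 13 adjusted over the list alone, but adjusted p = 0.185 with an estimated correlation and 0.0726 with quantile normalization). The deficient libraries also held a larger share of mitochondrial ribosomal RNA, which may depend on the depletion of ribosomal RNA. Of nuclear respiratory chain genes 14 of 32 tested fell and 18 did not pass (median -0.30, adjusted p = 0.00669, 14 adjusted over the list alone, but adjusted p = 0.0852 with an estimated correlation). Of metallothioneins 3 of 4 tested rose and 1 did not pass (median 0.88, adjusted p = 0.0257, 3 adjusted over the list alone, but adjusted p = 0.216 with an estimated correlation). The lists of pentose phosphate and nucleotide synthesis (median 0.19, adjusted p = 0.238), MondoA and ChREBP targets (0.82, 0.358) and fatty acid oxidation (-0.29, 0.285) did not pass. The same holds for the tricarboxylic acid cycle (-0.29, 0.0710), glycan and hexosamine synthesis (0.40, 0.0591) and apoptosis regulators (-0.07, 0.795). Serine synthesis and one-carbon metabolism (0.44, 0.405), NF-kB targets (-0.03, 0.592) and mesenchymal and matrix genes (-0.23, 0.844) did not pass either. In these 3 lists the mean had the opposite sign to the median and to the direction of the test. Among mesenchymal genes CCN1 rose by 2.17 ± 0.09. VEGFA (0.10 ± 0.10, adjusted p = 0.432) did not pass.

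In all, limma called 4804 of 9270 genes between deficient and full medium, 2440 higher and 2364 lower, 2208 of them by at least 2-fold. The balance of directions depended on the scaling: 50.8% of called genes were higher as deposited and 23.6% with libraries set to equal totals. On the recovered reads edgeR called 5004 genes and DESeq2 3938.

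The comparison of glucose-only with full medium asked what the loss of glutamine changed while glucose was present. Genes of sterol synthesis, glycolysis and the hypoxia response fell, and the amino acid response rose. INSIG1, a sterol-regulated brake on lipid synthesis (ENSG00000186480, chromosome 7, 155297878 to 155310235), fell from 227 ± 13.3 to 19.1 ± 5.48 (SD, n = 3). The glycolytic enzyme gene PGK1 (ENSG00000102144, chromosome X, 78104248 to 78129295) fell from 688 ± 38.4 to 122 ± 13.2, and the mitophagy receptor gene BNIP3 from 404 ± 16.1 to 56.0 ± 5.15. PSAT1, an enzyme of serine synthesis (ENSG00000135069, chromosome 9, 78297125 to 78330093), rose from 31.5 ± 4.52 to 195 ± 27.0, and TRIB3 from 13.5 ± 3.87 to 146 ± 5.32.

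Of the cholesterol synthesis genes 16 of 20 tested fell and 4 did not pass (median -1.67, adjusted p = 6.21e-21, 18 adjusted over the list alone). INSIG1 was at -3.54 ± 0.16, DHCR7 at -2.70 ± 0.21 and STARD4 at -2.71 ± 0.18. Of fatty acid and triglyceride synthesis genes 10 of 17 tested fell and 7 did not pass (median -0.72, adjusted p = 1.97e-11, 14 adjusted over the list alone), including SCD at -2.38 ± 0.10, FADS2 at -2.36 ± 0.14 and FASN at -1.28 ± 0.10. Of hypoxia targets 20 of 21 tested fell and 1 rose (median -1.36, adjusted p = 2.15e-22, 21 adjusted over the list alone), with BNIP3 at -2.83 ± 0.12 and NDRG1 at -2.17 ± 0.12. The member that rose was VEGFA, the vascular growth factor, at 0.55 ± 0.10. Of glycolysis genes 18 of 21 tested fell and 3 did not pass (median -1.13, adjusted p = 2.39e-20, 18 adjusted over the list alone), PGK1 by -2.49 ± 0.11 and TPI1 by -2.11 ± 0.10. All 32 tested mitosis genes fell (median -1.16, adjusted p = 1.13e-22, 32 adjusted over the list alone), with MKI67 at -1.15 ± 0.12. Of histone genes 26 of 28 tested fell and 2 did not pass (median -1.36, adjusted p = 2.68e-25, 26 adjusted over the list alone). Of DNA replication genes 7 of 30 tested fell and 23 did not pass (median -0.39, adjusted p = 0.00749, 8 adjusted over the list alone, but adjusted p = 0.125 with an estimated correlation). In the respiratory chain list 15 of 32 tested fell and 17 did not pass (median -0.46, adjusted p = 1.26e-06, 19 adjusted over the list alone), and in the tricarboxylic acid cycle 9 of 23 tested fell and 14 did not pass (median -0.35, adjusted p = 0.00662, 9 adjusted over the list alone). Of interferon-stimulated genes 8 of 13 tested fell, 1 rose and 4 did not pass (median -0.81, adjusted p = 0.00136, 10 adjusted over the list alone).

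Of the ATF4 targets 19 of 24 tested rose and 5 did not pass (median 1.43, adjusted p = 8.17e-24, 19 adjusted over the list alone), with TRIB3 at 3.38 ± 0.14, GDF15 at 3.03 ± 0.26 and CHAC1 at 2.85 ± 0.36. The ubiquitin ligase gene RBCK1 (2.40 ± 0.13) and the amino acid transporter gene SLC3A2 (2.02 ± 0.11) were among the 5 genes named for the highest values. Of tRNA synthetase genes 10 of 17 tested rose, 1 fell and 6 did not pass (median 0.60, adjusted p = 6.45e-10, 11 adjusted over the list alone). Of serine and one-carbon genes 5 of 11 tested rose, 1 fell and 5 did not pass (median 0.63, adjusted p = 0.000524, 6 adjusted over the list alone), PSAT1 by 2.59 ± 0.14 and SHMT2 by 1.14 ± 0.12. Of glutamine metabolism genes 7 of 14 tested rose, 2 fell and 5 did not pass (median 0.41, adjusted p = 0.00902, 11 adjusted over the list alone). The glutamine importer SLC1A5 was at 1.54 ± 0.13 and the glutamine synthetase GLUL at -0.71 ± 0.14. Of ribosome biogenesis genes 6 of 28 tested rose and 22 did not pass (median 0.33, adjusted p = 0.000123, 5 adjusted over the list alone). Of mitochondrial messenger RNAs 9 of 13 tested rose and 4 did not pass (median 0.42, adjusted p = 1.28e-07, 12 adjusted over the list alone, but adjusted p = 0.160 with an estimated correlation). Of ER chaperone genes 6 of 22 tested rose, 6 fell and 10 did not pass, and the list did not pass (median 0.04, adjusted p = 0.519, 14 adjusted over the list alone). The heat shock list did not pass either (median -0.27, adjusted p = 0.0720). TXNIP was at 0.58 ± 0.17 (adjusted p = 0.0149), with an adjusted p of 0.168 under equal totals. It was 0.0672 without full replicate A, 0.0535 without full replicate C and 0.0657 without glucose-only replicate B.

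Here limma called 2124 genes, 875 higher and 1249 lower, 648 by at least 2-fold, with 41.2% of them higher as deposited and 15.5% with equal totals. DESeq2 called 1255, of which 1248 were shared with limma in the same direction, and edgeR 2229.

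The comparison of glutamine-only with full medium asked what the loss of glucose changed while glutamine was present. ER chaperone genes rose, histone and mitosis genes fell, and cholesterol genes as a list did not pass. HSPA5 rose from 256 ± 15.3 to 1274 ± 31.6 (SD, n = 3), and HSP90B1, the ER form of HSP90, stood at 716 ± 42.9 and 2756 ± 11.96. TXNIP fell from 123 ± 9.24 to 9.36 ± 2.75. MKI67 fell from 533 ± 11.7 to 129 ± 8.28.

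Of the ER chaperone and unfolded protein response genes 21 of 22 tested rose and 1 did not pass (median 1.82, adjusted p = 2.87e-36, 21 adjusted over the list alone). HSPA5 was at 2.31 ± 0.09 and MANF, a secreted ER stress protein, at 2.23 ± 0.16. Of ATF4 targets 22 of 24 tested rose and 2 did not pass (median 1.60, adjusted p = 5.45e-30, 22 adjusted over the list alone). GDF15 was at 4.15 ± 0.26, TRIB3 at 3.32 ± 0.14 and SLC3A2 at 2.93 ± 0.11. Of tRNA synthetase genes 11 of 17 tested rose and 6 did not pass (median 0.58, adjusted p = 1.76e-10, 11 adjusted over the list alone), with WARS1 at 2.26 ± 0.12. Of serine and one-carbon genes 4 of 11 tested rose, 1 fell and 6 did not pass (median 0.57, adjusted p = 0.00976, 8 adjusted over the list alone), with PSAT1 at 2.47 ± 0.14. Of NRF2 targets 13 of 21 tested rose and 8 did not pass (median 0.69, adjusted p = 2.78e-10, 13 adjusted over the list alone). HMOX1 was at 3.45 ± 0.44 and the cystine transporter SLC7A11 at 1.62 ± 0.11. Of hexosamine and glycan synthesis genes 10 of 22 tested rose, 3 fell and 9 did not pass (median 0.48, adjusted p = 0.000979, 17 adjusted over the list alone). GFPT1, the entry enzyme of the hexosamine pathway, was at 2.08 ± 0.12. Of glutamine metabolism genes 7 of 14 tested rose, 1 fell and 6 did not pass (median 0.48, adjusted p = 0.000118, 10 adjusted over the list alone). Of ribosomal protein genes 36 of 48 tested rose and 12 did not pass (median 0.38, adjusted p = 6.02e-17, 44 adjusted over the list alone), and of lysosome genes 8 of 29 tested rose and 21 did not pass (median 0.32, adjusted p = 0.000371, 11 adjusted over the list alone). Of ribosome biogenesis genes 6 of 28 tested rose and 22 did not pass (median 0.19, adjusted p = 0.0110, 5 adjusted over the list alone). The last median was 0.31 without glutamine-only replicate A.

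All 28 tested histone genes fell (median -2.26, adjusted p = 4.90e-47, 28 adjusted over the list alone), with H3C3 at -2.61 ± 0.11 and H2BC5 at -2.09 ± 0.13. Of mitosis genes 30 of 32 tested fell and 2 did not pass (median -1.55, adjusted p = 4.84e-33, 31 adjusted over the list alone), with CCNA2 at -2.46 ± 0.27. Of DNA replication genes 24 of 30 tested fell and 6 did not pass (median -1.16, adjusted p = 5.87e-15, 27 adjusted over the list alone), with RRM2 at -2.12 ± 0.20. The MondoA and ChREBP targets fell as a list (4 of 6 tested fell and 2 did not pass, median -0.57, adjusted p = 0.00637, 4 adjusted over the list alone), with TXNIP at -3.61 ± 0.17. Of glycolysis genes 13 of 21 tested fell, 1 rose and 7 did not pass (median -0.48, adjusted p = 6.33e-05, 15 adjusted over the list alone), with PGK1 at -1.02 ± 0.11. Of NF-kB targets 7 of 19 tested fell, 2 rose and 10 did not pass (median -0.42, adjusted p = 0.00959, 9 adjusted over the list alone), with the chemokine CXCL1 at -2.62 ± 0.25. Of interferon-stimulated genes 6 of 13 tested fell, 1 rose and 6 did not pass (median -1.10, adjusted p = 0.00714, 8 adjusted over the list alone). Of cholesterol synthesis genes 1 of 20 tested rose, 1 fell and 18 did not pass (median 0.05, adjusted p = 0.674, 2 adjusted over the list alone). Another 3 lists passed with the preset correlation alone. They were mitochondrial messenger RNAs (13 of 13 tested rose, median 0.58, adjusted p = 0.0730 with an estimated correlation), respiratory chain genes (8 of 32 tested fell and 24 did not pass, median -0.30, adjusted p = 0.0670 with an estimated correlation) and heat shock genes (4 of 14 tested rose and 10 did not pass, median 0.18, adjusted p = 0.0570 with an estimated correlation). The heat shock adjusted p was also 0.0832 with equal totals and 0.0610 with a constant prior variance. DNAJB1 rose by 1.31 ± 0.11.

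Here limma called 2083 genes, 1005 higher and 1078 lower, 671 by at least 2-fold, with 48.2% of them higher as deposited and 31.6% with equal totals. DESeq2 called 1399 and edgeR 2446.

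The single-nutrient media were then set against each other. Glucose-only cells had lower ER chaperone, sterol and lipid synthesis and hypoxia genes than glutamine-only cells, and higher TXNIP and histone genes. TXNIP stood at 185 ± 10.5 with glucose and 9.36 ± 2.75 with glutamine (SD, n = 3), a log2 difference of 4.19 ± 0.17. INSIG1 stood at 19.1 ± 5.48 and 279.8 ± 11.8, and SCD at 129.9 ± 19.1 and 990.1 ± 41.7. HSP90B1 stood at 534 ± 20.9 and 2756 ± 11.96, and the ER oxidoreductase gene PDIA3 at 72.0 ± 11.6 and 365 ± 22.2.

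**Figure D2:**
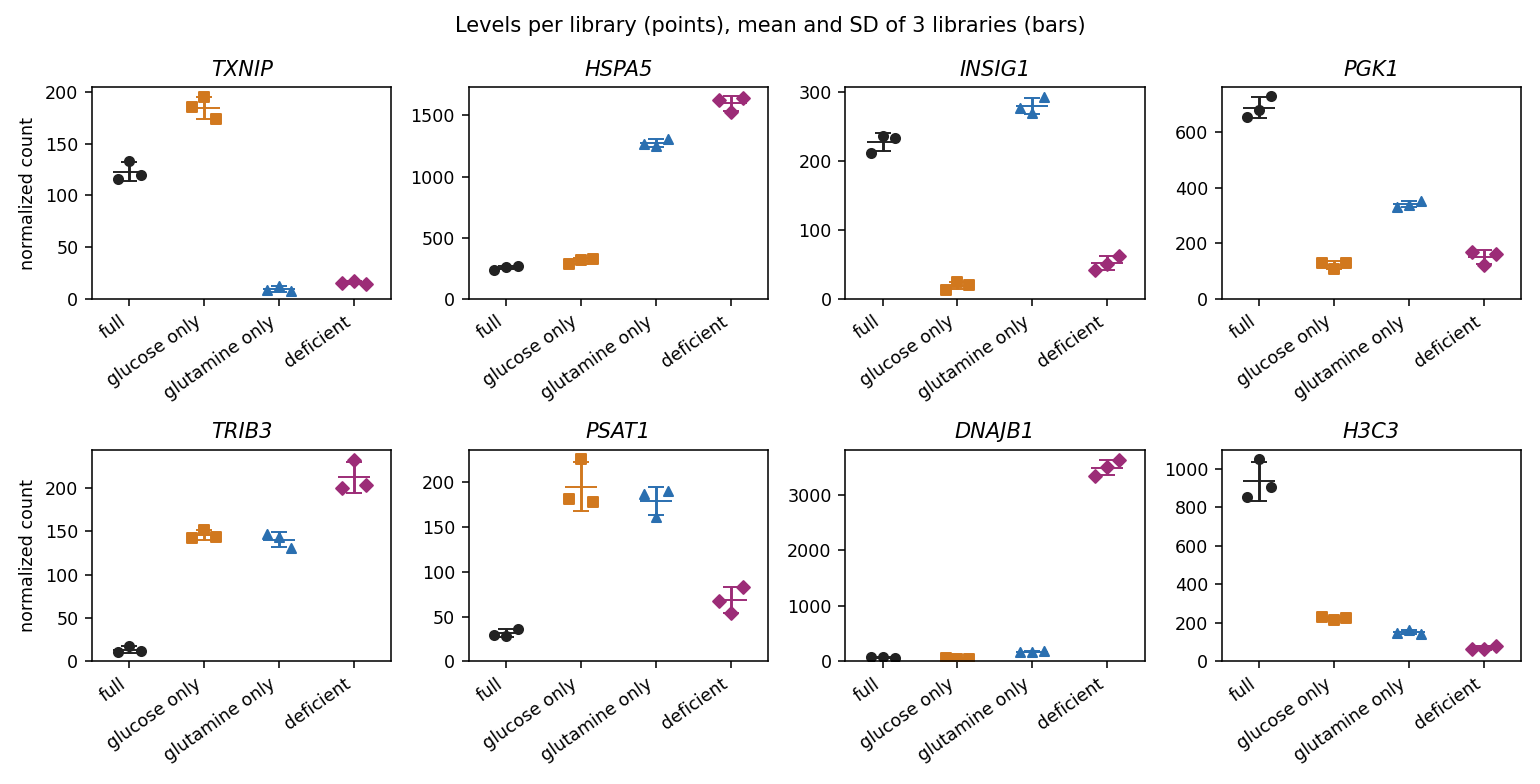
Normalized count of 8 genes per library (points) with the mean and SD of 3 libraries (bars) in each medium, each axis starting at 0. TXNIP is at 123 and 185 in the media with glucose and at 9.36 and 15.8 in those without, and DNAJB1 reaches 3487 in the deficient medium.

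Of ER chaperone genes 19 of 22 tested were lower, 1 was higher and 2 did not pass in glucose-only cells (median -1.89, adjusted p = 5.59e-38, 20 adjusted over the list alone), with MANF at -2.84 ± 0.16 and HSPA5 at -2.04 ± 0.09. Of cholesterol genes 15 of 20 tested were lower and 5 did not pass (median -1.59, adjusted p = 4.07e-28, 17 adjusted over the list alone). INSIG1 was at -3.84 ± 0.16 and HMGCS1, which makes the precursor of mevalonate, at -2.17 ± 0.19. Of fatty acid and triglyceride synthesis genes 12 of 17 tested were lower, 1 was higher and 4 did not pass (median -1.15, adjusted p = 1.40e-16, 14 adjusted over the list alone), and of hypoxia targets 18 of 21 tested were lower and 3 did not pass (median -1.11, adjusted p = 2.09e-27, 20 adjusted over the list alone). Of glycolysis genes 15 of 21 tested were lower and 6 did not pass (median -0.72, adjusted p = 6.89e-17, 19 adjusted over the list alone), PGK1 by -1.47 ± 0.11. Of NRF2 targets 15 of 21 tested were lower and 6 did not pass (median -0.62, adjusted p = 1.86e-14, 16 adjusted over the list alone), and of ribosomal protein genes 37 of 48 tested were lower and 11 did not pass (median -0.43, adjusted p = 3.26e-25, 43 adjusted over the list alone). Of heat shock genes 6 of 14 tested were lower and 8 did not pass (median -0.27, adjusted p = 1.25e-05, 8 adjusted over the list alone). Of ATF4 targets 7 of 24 tested were lower and 17 did not pass (median -0.26, adjusted p = 0.00491, 7 adjusted over the list alone), and of glutamine metabolism genes 5 of 14 tested were lower and 9 did not pass (median -0.20, adjusted p = 0.0169, 5 adjusted over the list alone). The ATF4 target TRIB3 (0.05 ± 0.14, adjusted p = 0.864) and PSAT1 of the serine list (0.12 ± 0.14, adjusted p = 0.666) did not pass.

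Of histone genes 24 of 28 tested were higher and 4 did not pass in glucose-only cells (median 0.87, adjusted p = 5.77e-21, 25 adjusted over the list alone). Of DNA replication genes 13 of 30 tested were higher and 17 did not pass (median 0.71, adjusted p = 1.73e-11, 19 adjusted over the list alone). Of mitosis genes 7 of 32 tested were higher and 25 did not pass (median 0.36, adjusted p = 1.84e-06, 9 adjusted over the list alone), MKI67 by 0.89 ± 0.12. The respiratory chain list was lower (6 of 32 tested were lower, 1 was higher and 25 did not pass, median -0.24, adjusted p = 0.00875, 9 adjusted over the list alone, but adjusted p = 0.0910 with an estimated correlation). In all, 18 lists were called in this comparison, 4 higher and 14 lower, and 17 of them also with an estimated correlation. Not every called list is described here, and the growth arrest genes are among those left out. The 5 genes named for the highest values were mitochondrial tRNA genes, among them MT-TR at 1.33 ± 0.19 and MT-TG at 1.12 ± 0.21. Nuclear short RNA genes had a median of 0.31 in the same comparison.

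The test called 1234 genes, 468 higher and 766 lower in glucose-only cells, 347 by at least 2-fold, with 37.9% of them higher as deposited and 21.3% with equal totals. DESeq2 called 604 genes, 601 of them shared in the same direction, edgeR 1251, and a constant prior variance gave 817.

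**Figure D3:**
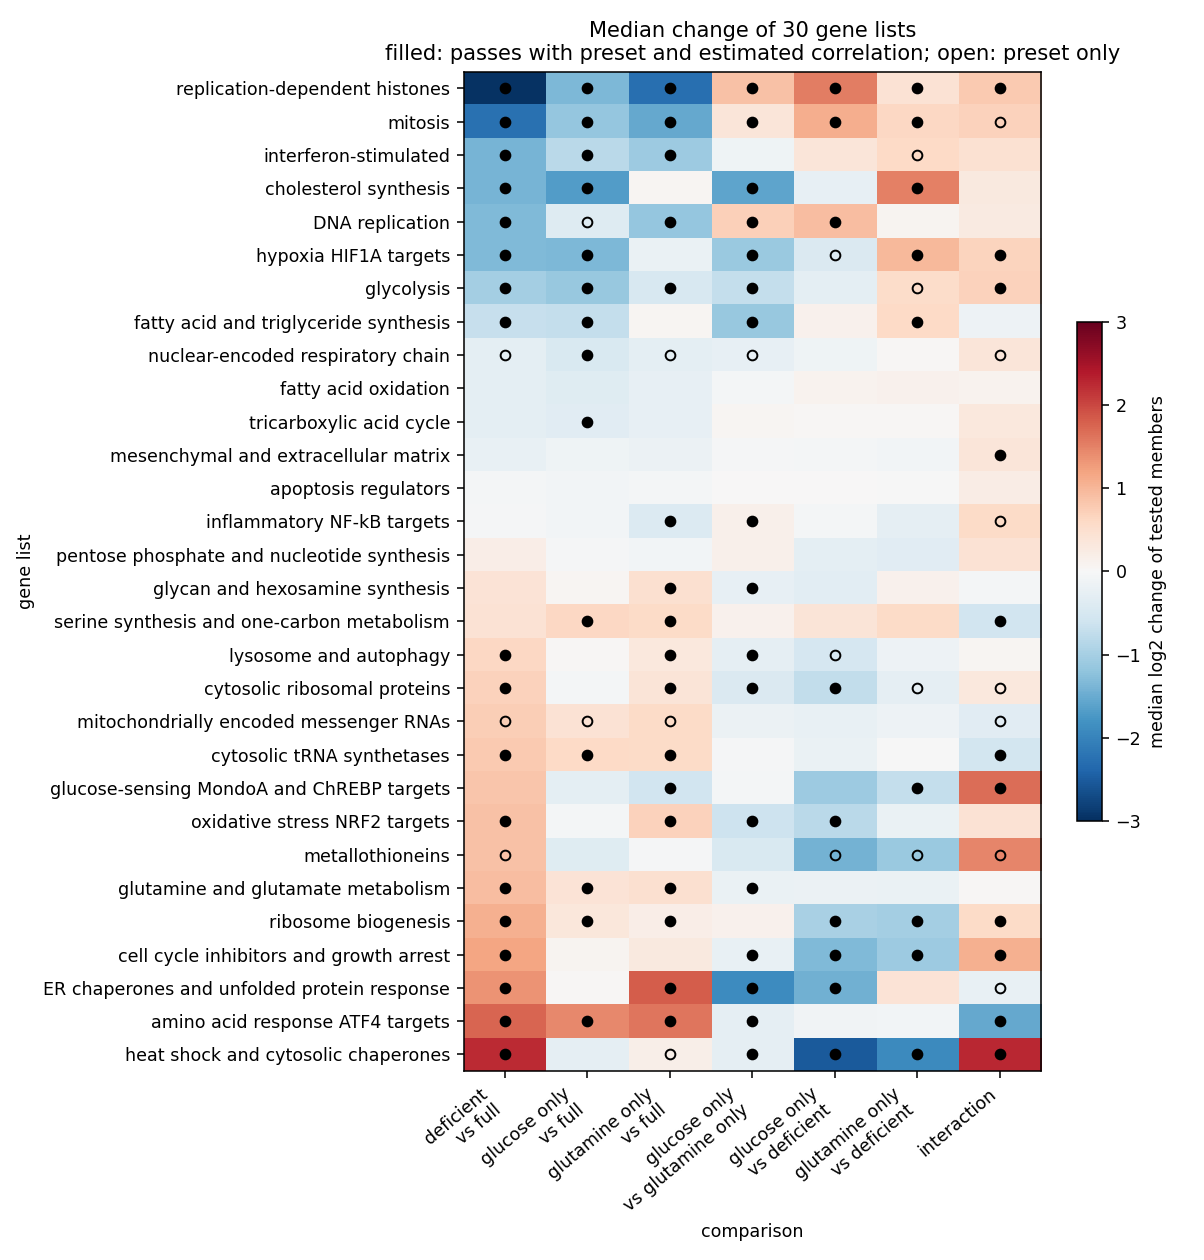
Median log2 change of the tested members of 30 gene lists (vertical) in 6 comparisons and the interaction (horizontal). Filled circles mark lists passing adjusted p under 0.05 with the preset and the estimated correlation and open circles those passing with the preset value alone, and the heat shock list reads 2.24 in deficient against full and -2.52 in glucose-only against deficient.

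The next comparisons asked what each nutrient changed when given alone. Heat shock genes were lower with either nutrient than with neither: DNAJB1 stood at 3487 ± 138 without nutrients, at 55.7 ± 8.13 with glucose and at 174 ± 12.5 with glutamine (SD, n = 3). All 14 tested heat shock genes were lower with glucose (median -2.52, adjusted p = 2.73e-23, 14 adjusted over the list alone) and all 14 with glutamine (median -1.90, adjusted p = 1.59e-22, 14 adjusted over the list alone). Of ribosome biogenesis genes 23 of 28 tested were lower and 5 did not pass with glucose (median -0.97, adjusted p = 8.95e-08, 25 adjusted over the list alone). With glutamine 26 of 28 tested were lower and 2 did not pass (median -1.02, adjusted p = 1.35e-10, 26 adjusted over the list alone). MYC was at -1.87 ± 0.12 and -2.11 ± 0.12. Of growth arrest genes 13 of 16 tested were lower and 3 did not pass with glucose (median -1.32, adjusted p = 1.43e-06, 14 adjusted over the list alone). With glutamine 11 of 16 tested were lower, 2 were higher and 3 did not pass (median -1.09, adjusted p = 0.000348, 13 adjusted over the list alone). The cell cycle inhibitor CDKN1A was at -1.59 ± 0.13 and -1.35 ± 0.13.

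Of ER chaperone genes 19 of 22 tested were lower and 3 did not pass with glucose (median -1.44, adjusted p = 1.25e-14, 19 adjusted over the list alone), HSPA5 by -2.37 ± 0.09. Of ribosomal protein genes 47 of 48 tested were lower and 1 did not pass (median -0.74, adjusted p = 8.62e-23, 47 adjusted over the list alone). Of NRF2 targets 16 of 21 tested were lower, 2 were higher and 3 did not pass (median -0.81, adjusted p = 8.95e-08, 19 adjusted over the list alone), HMOX1 by -6.74 ± 0.44. All 28 tested histone genes were higher (median 1.53, adjusted p = 5.30e-19, 28 adjusted over the list alone). Of mitosis genes 22 of 32 tested were higher and 10 did not pass (median 1.09, adjusted p = 4.62e-11, 26 adjusted over the list alone), and of DNA replication genes 21 of 30 tested were higher and 9 did not pass (median 0.92, adjusted p = 3.25e-07, 21 adjusted over the list alone). TXNIP was higher by 3.47 ± 0.17, the laminin gene LAMA5 by 1.97 ± 0.11 and DPYSL2 by 1.93 ± 0.11. Another 3 lists were called lower with the preset correlation alone. Of lysosome genes 13 of 29 tested were lower, 4 were higher and 12 did not pass (adjusted p = 0.0538 with an estimated correlation), and of metallothioneins 4 of 4 tested were lower (adjusted p = 0.146 with an estimated correlation). Of hypoxia targets 11 of 21 tested were lower, 3 were higher and 7 did not pass (adjusted p = 0.0649 with an estimated correlation, 0.0520 in a fit on the 2 groups alone and 0.0503 without glucose-only replicate A).

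Of cholesterol genes 17 of 20 tested were higher and 3 did not pass with glutamine (median 1.504, adjusted p = 2.78e-11, 17 adjusted over the list alone). Of fatty acid and triglyceride synthesis genes 10 of 17 tested were higher, 2 were lower and 5 did not pass (median 0.61, adjusted p = 5.95e-06, 13 adjusted over the list alone). Of hypoxia targets 14 of 21 tested were higher, 4 were lower and 3 did not pass (median 0.98, adjusted p = 1.00e-05, 18 adjusted over the list alone). SCD was at 3.00 ± 0.10 and INSIG1 at 2.44 ± 0.16. Of mitosis genes 19 of 32 tested were higher, 1 was lower and 12 did not pass (median 0.63, adjusted p = 1.38e-05, 21 adjusted over the list alone), and of histone genes 16 of 28 tested were higher and 12 did not pass (median 0.44, adjusted p = 1.38e-05, 17 adjusted over the list alone). All 6 tested MondoA and ChREBP targets were lower (median -0.72, adjusted p = 0.00126, 6 adjusted over the list alone), with KLF10 at -2.05 ± 0.13. Among lists called with the preset correlation alone, 13 of 21 tested were higher, 4 were lower and 4 did not pass for glycolysis (adjusted p = 0.0872 with an estimated correlation) and 4 of 4 tested were lower for metallothioneins (adjusted p = 0.208 with an estimated correlation). Of ribosomal protein genes 29 of 48 tested were lower, 1 was higher and 18 did not pass (adjusted p = 0.217 with an estimated correlation, 0.0557 with equal totals, where the median was 0.0030, and 0.648 with quantile normalization). For glutamine alone 13 lists were called, 7 higher and 6 lower, and 9 of them also with an estimated correlation. Not every one of them is described here.

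Against the deficient medium limma called 4008 genes for glucose alone (1859 higher, 2149 lower) and 3844 for glutamine alone (1844 higher, 2000 lower). Of the called genes 46.4% and 48.0% were higher as deposited, and 63.5% and 75.0% with equal totals. DESeq2 called 2756 and 2757, and edgeR 3900 and 3893.

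The title of the series names separate glucose-dependent and glutamine-dependent states, and the last comparisons asked how far the effects of the nutrients were separate across genes. A positive interaction means that the full and deficient media together had higher log2 values than the 2 single-nutrient media together. Of heat shock genes all 14 tested members were positive (median 2.26, adjusted p = 6.47e-26, 14 adjusted over the list alone), with DNAJB1 at 4.64 ± 0.15, HSPH1 at 3.50 ± 0.18 and HSP90AA1 at 3.38 ± 0.14. Of ATF4 targets 17 of 24 tested were negative, 1 was positive and 6 did not pass (median -1.53, adjusted p = 1.01e-12, 20 adjusted over the list alone). PSAT1, of the serine list, was at -3.99 ± 0.21: it stood at 31.5 ± 4.52 in full medium, 195 ± 27.0 and 179 ± 16.02 with either nutrient alone and 68.4 ± 14.4 with neither (SD, n = 3). RBCK1 was at -2.92 ± 0.18 and TRIB3 at -2.79 ± 0.20. For TXNIP the interaction was 0.14 ± 0.25 (adjusted p = 0.721), and for HSPA5 0.06 ± 0.13 (adjusted p = 0.785).

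The interaction passed for 2458 genes, 1438 positive and 1020 negative. Of these, 1832 had their highest (1081) or lowest (751) mean in the deficient medium. The sign of the glucose effect, with both effects past the threshold, was opposite with and without glutamine for 289 of them, and that of the glutamine effect for 341. Of the called genes 58.5% were positive as deposited and 45.7% with quantile normalization. DESeq2 called 1495 genes, 1494 of them shared in the same direction, and edgeR 2524.

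Averaged over the other nutrient, glucose changed 3602 genes (1703 higher, 1899 lower) and glutamine 3531 (1809 higher, 1722 lower). Of these 47.3% and 51.2% were higher as deposited, and 67.6% and 82.6% with equal totals. Histone genes were higher with both glucose (28 of 28 tested were higher, median 1.86, adjusted p = 5.51e-35, 28 adjusted over the list alone) and glutamine (26 of 28 tested were higher and 2 did not pass, median 0.92, adjusted p = 3.57e-18, 28 adjusted over the list alone). ER chaperone genes were lower with glucose (22 of 22 tested were lower, median -1.57, adjusted p = 1.97e-26, 22 adjusted over the list alone) and did not pass for glutamine (median 0.36, adjusted p = 0.240). Cholesterol genes were higher with glutamine (17 of 20 tested were higher and 3 did not pass, median 1.53, adjusted p = 2.26e-18, 18 adjusted over the list alone) and did not pass for glucose (median -0.24, adjusted p = 0.225). These differences between the nutrients are tested by glucose-only against glutamine-only, where both lists passed.

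Across the 9270 genes, which are not independent replicates, the average glucose and glutamine effects correlated with r = 0.60 (jackknife SE 0.0520 over libraries), where simulated data without effects gave -0.037 to 0.036. Both effects were positive and called for 955 genes, against 332 for independent lists of these sizes, and both negative for 969 against 353. A gene that changed only in the deficient medium counts in both average effects with the same sign. The correlation and these overlaps therefore do not show how far the nutrients act separately. The simulated data held no effects and cannot address this. The glutamine effect with glucose and that without, which share no library, correlated with r = 0.23, and the glucose effect with and without glutamine with r = 0.33. Without a filter, over 32493 genes, the 3 correlations were 0.40, 0.11 and 0.17, and the last 2 were 0.33 and 0.43 among genes with a mean of at least 100.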

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

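The tests on heat shock genes, mitochondrial tRNA genes and genes listed near 0 were chosen only after the results were seen, and the splits and regroupings of libraries before. Each flagged gene had a glucose effect that differed with and without glutamine, tested by full minus glucose-only minus glutamine-only plus deficient. Each flagged list passed camera on the same contrast, so that its call is relative to all other genes. The test of single genes passed for 2458 of 9270 genes. In 100 drawn groupings of the 12 libraries, the real one included, the real grouping alone (1) gave as many. The highest other gave 672. For the average glucose effect the real value was 3602 and the highest other 1874 (1 of 100 as large). For the average glutamine effect the values were 3531 and 1320 (1 of 100). The other draws mixed libraries of different media, so that differences between media entered the spread within groups. The draws therefore argue only against the case that no medium had any effect. They cannot test the interaction or either average effect on its own. Whether the libraries of a medium were separate cultures is not stated, so that chance differences between cultures stay open.

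The 6 comparisons between media allow 10 splits each, too few for a share under 0.05, and the real split was the 1 with the most genes in each. The real value and the highest other were 4804 and 0 for deficient against full, 2124 and 1 for glucose-only against full, and 2083 and 0 for glutamine-only against full. They were 1234 and 0 for glucose-only against glutamine-only, 4008 and 0 for glucose-only against deficient, and 3844 and 0 for glutamine-only against deficient. The other splits mixed libraries of both media, so that the difference between media entered the spread within groups. Their counts near 0 therefore add no support to any comparison.

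The interaction, in log2, was negative for PSAT1 (-3.99), RBCK1 (-2.92), TRIB3 (-2.79), GDF15 (-2.58), CHAC1 (-2.24), SLC7A11 (-1.93), VEGFA (-1.07) and SCD (-0.62). It was positive for DNAJB1 (4.64), HSPH1 (3.50), HSP90AA1 (3.38), HK2 (2.28), CDKN1A (2.02), GLUL (1.67) and HMGCS1 (1.25). For MKI67 it was 0.51, below the threshold without deficient replicate B (0.36), full replicate A (0.49), glucose-only replicate C (0.45), glutamine-only replicate A (0.49) or glutamine-only replicate B (0.47), and with DESeq2, a constant prior variance, no filter, equal totals, protein-coding scaling or quantile normalization. For PHGDH it was -2.10, and the call was lost without deficient replicate A (-1.85) or B (-2.03), full replicate C (-1.69), glucose-only replicate A (-1.77) or C (-1.98), or glutamine-only replicate B (-1.86) or C (-1.82), and with a constant prior variance or quantile normalization.

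Among the lists, the median interaction was 2.26 for heat shock genes, 1.67 for MondoA and ChREBP targets and 1.06 for growth arrest genes. It was 0.79 for histones, 0.68 for glycolysis, 0.67 for HIF1A targets and 0.57 for ribosome biogenesis. Among MondoA and ChREBP targets the largest values were PDK4 (3.82), BHLHE40 (2.30), KLF10 (2.02) and ARRDC3 (1.32), and TXNIP did not pass (0.14, adjusted p = 0.721). The median was 0.36 for mesenchymal genes, with an adjusted p of 0.0924 under quantile normalization. It was -1.53 for ATF4 targets and -0.55 for tRNA synthetases. For serine and one-carbon metabolism it was -0.57, and -0.26 without deficient replicate A, -0.89 without deficient replicate B and -0.33 without full replicate B. These 11 lists also passed with an estimated correlation, and another 7 did not. These were metallothioneins (1.46, adjusted p = 0.120 with an estimated correlation), mitosis (0.68, 0.0582), NF-kB targets (0.58, 0.0686) and the respiratory chain (0.36, 0.120, with a median of 0.24 without glucose-only replicate B). The others were ribosomal proteins (0.32, 0.239, with a median of -0.036 under quantile normalization), ER chaperones (-0.21, 0.0686, with a median of -0.14 without glucose-only replicate B) and mitochondrial messenger RNAs (-0.34, 0.395).

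Heat shock genes were higher in the deficient libraries, and a difference in scaling, a single deviating library or a difference in depth and composition were weighed against an effect of the medium. The lowest list median for deficient against full over 3 other scalings was 1.84. Against the full-medium mean, the lowest of the 3 deficient libraries was at 2.22 and the highest of the other 9 at 0.25, glucose-only libraries with the lowest protein-coding share included. These values argue against scaling, a single deviating library and a difference in depth or protein-coding share as the whole cause. Mitochondrial ribosomal RNA took at least 15.3% of reads in each deficient library and at most 14.2% in any other. The other libraries therefore cannot test that part of the composition. An effect of the missing nutrients may account for the pattern, as a hypothesis found and tested on the same libraries.

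Mitochondrial tRNA genes were higher in the glucose-only libraries against full (median 0.98 ± 0.06, bootstrap SE over 19 genes, and 0.58 to 1.02 over 3 other scalings) and glutamine-only (0.78, and 0.43 to 0.80), and also in deficient against full (0.65, and 0.24 to 0.67), but not past the threshold against deficient (0.28, adjusted p = 0.0750). The first 3 list tests were lost with an estimated correlation (adjusted p = 0.183, 0.329 and 0.829). Recovery of short RNAs as the whole cause would need nuclear short RNAs to move alike. Against full their median was 0.20, and -0.01 to 0.25 over the other scalings, which argues against a recovery common to all of them. SnoRNA genes alone were at 0.43 against 0.98 for the mitochondrial tRNA genes. With quantile normalization they were at 0.52 against 0.58, so that recovery stays open. Against glutamine-only the median of nuclear short RNA genes was 0.31, and 0.36 with quantile normalization, so that recovery stays open there too. More mitochondrial RNA of every kind would need higher mitochondrial messenger RNAs, and their median was -0.19 against glutamine-only, which argues against it there, but 0.42 ± 0.05 against full, where it was 0.20 with equal totals and 0.15 with quantile normalization, so that the answer depends on the scaling and stays open. An effect of the medium may contribute beside a share of either explanation.

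Of 307 members of 10 lists of broadly used genes, 11 had a mean under 1: COX5B, E2F2, LDHA, NDUFB10, NDUFS3, NSDHL, RPS18, RPS25, RRN3, SDHB and SLC16A1. On an older annotation 0% of the 11 shared most of their exonic bases with another gene on the same strand (upper 95% limit 28.5%). This argues against shared exons as the cause for most of them on that annotation. Overlaps in the later annotation behind the file cannot be seen, so that this cause stays open. Of protein-coding genes with over 90% of exonic bases shared, 86.7% were at 0. Of those sharing none it was 20.4%. Reads lost over whole stretches may be a cause. Of the neighbours of 10 of the 11, 90% (18 of 20) were near 0 too. Beside 217 measured members it was 26.7% (116 of 434, Fisher's exact one-sided unadjusted p = 1.31e-08). Members and neighbours counted here were protein-coding genes that share no exonic base on the same strand. In the major histocompatibility region (chromosome 6, 29000000 to 33000000) 0 of 94 such genes reached a mean of 10, against 332 of 772 such genes on the rest of the chromosome (Fisher's exact one-sided unadjusted p = 5.69e-22). No biological explanation was tested, and where the reads were lost stays open.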

How the results depend on the processing

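Scaling on protein-coding genes and the fit on nuclear protein-coding genes were chosen only after the results were seen. All 9 counts of genes stayed within 1.5 times the reported count under equal totals, quantile normalization, both pseudocounts, no filter, edgeR, the replicate block and both added alternatives, and the 6 counts between media in fits on the 2 groups alone. Depth limits what can be called: a mean of at least 100 left 1213 genes.

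With that stricter filter the counts, from fewer genes tested, were 903 for deficient against full, 615 for glucose-only against full, 624 for glutamine-only against full, 486 for glucose-only against glutamine-only, 776 and 777 for glucose-only and glutamine-only against deficient, 632 for the interaction, and 806 and 774 for the average glucose and glutamine effects. At an adjusted p under 0.01, a stricter threshold, they were 1245 for glucose-only against full, 1276 for glutamine-only against full, 656 for glucose-only against glutamine-only and 1496 for the interaction. DESeq2 gave 1255 for glucose-only against full, 604 for glucose-only against glutamine-only and 1495 for the interaction, and a constant prior variance 817 for glucose-only against glutamine-only; the cause was not tested.

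The correlation of the average effects was 0.396 with no filter and 0.542 with quantile normalization. That of the glucose effect with and without glutamine was 0.434 at a mean of at least 100, 0.171 with no filter, 0.301 with quantile normalization, 0.355 with DESeq2, 0.357 with edgeR and 0.346 on nuclear protein-coding genes. That of the glutamine effect was 0.332 at a mean of at least 100, 0.114 with no filter and 0.214 with quantile normalization. The cause was not tested.

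Leaving out 1 library gave 4261 to 4844 genes for deficient against full, 1640 to 2225 for glucose-only against full, 1637 to 2194 for glutamine-only against full, 849 to 1327 for glucose-only against glutamine-only, 3488 to 3992 and 3236 to 3870 for glucose-only and glutamine-only against deficient, 2143 to 2443 for the interaction, and 3233 to 3497 and 3119 to 3377 for the average glucose and glutamine effects. The correlations were 0.570 to 0.612, 0.314 (without full replicate A) to 0.329 for the glucose effect, and 0.221 to 0.238 for the glutamine effect.

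Directions reversed, none past the threshold, for 7 results. For a list this is the direction of camera, and the values in brackets are medians. At a mean of at least 100, which left 1 to 6 members, these were DNA replication in glucose-only against full (0.14), NF-kB targets in glutamine-only against full (0.00066) and growth arrest genes in glucose-only against glutamine-only (0.026). Lysosome genes were also among them, in deficient against full (0.041) and in glucose-only against deficient (-0.030). Both lysosome medians still lay on the side reported above, so that only the direction of the test reversed. The others were ribosomal proteins in the interaction with quantile normalization (-0.036) and MT-ND6 in glutamine-only against deficient with equal totals (0.017); their cause was not tested.

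Of 210 list tests, 23 lost their call with an estimated correlation and 61 gained it with fry, which asks another question; 34 lost it at a mean of at least 100 and 39 gained it with no filter. Among tests of named genes, DESeq2 ended 96 calls, a constant prior variance 66, equal totals 53, quantile normalization 46, no filter 44 and edgeR 20. Libraries that share a replicate letter were checked for a common deviation. Over 18 such pairs between media the mean correlation was 0.0150 (-0.0289 to 0.067), against -0.0075 for pairs with different letters. Of the pairs sharing a letter 0 passed 0.1. Still, 8 of 12 libraries correlated best with their own letter, so that a small shared deviation stays open. A block for the letter gave 4863, 2166, 2135, 1276, 4036, 3874, 2492, 3637 and 3576 genes, in the order in which the counts are given for left-out libraries.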

Other observations

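The tests of RNA classes in this part were chosen only after the results were seen. Long noncoding RNA genes stand in none of the fixed lists, and as a class they were higher after the loss of either nutrient. Of 276 tested, 71 rose and 10 fell in glucose-only against full medium (median 0.38 ± 0.05, bootstrap SE over genes, adjusted p = 1.77e-08), and 86 rose and 6 fell in glutamine-only against full medium (median 0.43 ± 0.04, adjusted p = 6.33e-09). In deficient against full medium 70 rose and 72 fell (median -0.04 ± 0.08, adjusted p = 0.907), a median that was -0.40 with equal totals and 0.08 with quantile normalization. The difference itself passed, with a median interaction of -0.82 ± 0.08, 102 genes negative and 11 positive (adjusted p = 1.21e-12, and 5.90e-06 with an estimated correlation). Over equal totals, quantile normalization and protein-coding scaling the median was 0.17 to 0.42 for glucose-only against full, 0.33 to 0.46 for glutamine-only against full and -0.88 to -0.76 for the interaction.

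Small nucleolar RNA genes, which guide modification of ribosomal RNA, rose in 69 of 113 and fell in 2 in deficient against full medium (median 0.48 ± 0.03, adjusted p = 4.46e-07, but adjusted p = 0.829 with an estimated correlation). With equal totals this median was 0.08. In glucose-only against full medium 64 rose and 1 fell (median 0.43 ± 0.03, adjusted p = 3.37e-18, but 0.261 with an estimated correlation). With equal totals this median was 0.22.

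Several genes of interest for these media had values too low to test. LDHA, the lactate dehydrogenase subunit gene (ENSG00000134333, chromosome 11, 18394563 to 18408425), was listed at 0 in 11 of 12 libraries, with 1.83 in the other. ASNS, the asparagine synthetase gene, was listed at 0.917 to 12.9, and ARRDC4, a relative of TXNIP, at 0 to 7.05 with 7 libraries at 0. RPS25 and COX5B were listed at 0 in all 12 libraries. LDHA, RPS25 and COX5B are among the genes near 0 whose reads may have been lost over whole stretches. Their values do not show that they were silent. ASNS and ARRDC4 were not part of that check, and overlaps in the later annotation behind the file cannot be seen. The low values of ASNS and ARRDC4 therefore do not show low expression either.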
